A study of Homo sapiens with 20 samples.

How the data were processed

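ATAC-seq maps open chromatin by the insertion of sequencing adapters with the Tn5 transposase. The material was H1, an established human embryonic stem cell line, put through neural induction by dual SMAD inhibition, in which the BMP and the activin/NODAL branches of TGF-beta signalling are blocked together, for up to 72 h. Per the labels' protocols, 50000 nuclei went into each library. The 20 libraries form 2 sets. The set labelled 3TP holds libraries of 0, 3 and 72 h, and the set labelled 7TP holds libraries of 0, 3, 6, 12, 24, 48 and 72 h, with 2 replicates per time, which makes 10 groups. The labels do not say that replicates came from separate cultures, so p-values of tests over libraries measure the spread between these libraries, which may be technical.

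Per the submitters' processing notes, reads were handled with FastQC, Trimmomatic, Bowtie2 2.2.9, Picard and MACS2 2.1.0 on the hg19 build. The notes give neither settings nor an order, and no step that shifts reads for the Tn5 offset or removes mitochondrial reads is given in the sources used here. Each deposited file is one library's peak list in the narrowPeak layout, so peaks were called per sample. The fold (ratio) of each peak over its background, the −log10 p-value and −log10 q-value of each peak, and the integer score are the authors' deposited values. The last column of the deposited lists, the offset of the summit from the peak's start, is a position and belongs to no measurement scale. The lowest deposited −log10 q in the lists lay between 1.30 and 1.33, just above 1.30, the value of a q of 0.05. Read counts and depth are unknown, so no counting error can be given, and the fold and the q of a peak were used only to rank peaks within their own list. Median peak width was 240 ± 36.7 bp (SD, n = 6) in the 3TP set and 407 ± 28.1 bp (SD, n = 14) in the 7TP set. Lists of the 3TP set each held 2 peaks on the mitochondrial chromosome and lists of the 7TP set held 0, and the names given to the peaks followed another pattern in each set. These differences may come from library preparation, depth or processing, which the labels do not tell apart. Counts of regions gained or lost between 2 times were repeated within each set, and late against early within the 7TP set alone. Motif and gene list tests were not repeated within a set, apart from the octamer at 3 h.

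The deposited lists held 29263 to 57383 peaks. Each list was shortened to its 29263 best peaks by −log10 q, the length of the shortest list, so that a longer list could not hold more regions merely through its length. Windows of 501 bp were centred on summits of chromosomes 1 to 22 and X, taken by best rank without overlap, which gave 93863 regions found in at least 1 library. A library was taken to have a region when one of its peaks overlapped the window by at least 100 bp. Because all lists had the same length, the number of regions gained cannot show a net opening or closing of chromatin.

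Comparisons were of 3 kinds. For 72 h against 0 h, 3 h against 0 h and 72 h against 3 h, a region was counted as gained or lost when it was present in all 4 libraries of one time and in 0 of the 4 libraries of the other, over both sets. No test per region can pass correction with 4 against 4, so the counts were compared with those of the 35 splits of the 8 libraries. For late (24, 48 and 72 h, 8 libraries) against early (0, 3 and 6 h, 10 libraries), regions present in 4 to 14 of the 18 libraries were tested with an exact Fisher test of presence stratified by set, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. For the time course, regions were defined in the 3TP set alone and their share was measured in each library of the 7TP set, with Pearson and Spearman correlations with time and a permutation test of 100000 draws. Similarity of libraries was the Jaccard index, the regions shared by a pair divided by the regions in either, with a permutation of the times within each set.

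Peaks were placed on the GRCh37 genome, which is the same assembly as hg19, with the GENCODE 44 annotation lifted to it. Of the peaks on chromosomes 1 to 22 and X, 0 ended beyond the chromosome's length. Each region was assigned to the nearest protein-coding transcription start site (TSS) within 100 kb. The 15 gene lists, with 213 distinct genes of which 1 was not found in the annotation, were pluripotency, neural ectoderm regulators, SMAD pathway targets, mesendoderm, trophoblast and surface ectoderm, neural crest and placode, WNT pathway, NOTCH pathway, FGF and ERK feedback, immediate early, neuronal differentiation, HOX and posterior, fibroblast and mesenchyme, blood and endothelium, and housekeeping. The share of a list's tested regions that was called was compared with 10000 random gene lists matched on tested regions per gene, two-sided, with adjustment over 30 tests. At 72 h against 0 h the HOX list had no region in exactly 4 of the 8 libraries, and adjustment was over 28 tests. Presence of 26 consensus motifs on either strand was scored in the central 201 bp of a window, and called regions were compared with the other tested regions by the Cochran-Mantel-Haenszel test over 10 GC strata, with adjustment over 52 tests. Regions are not independent samples, so p-values for motifs and for promoter shares describe these region sets and not a spread between libraries or cultures. Those of gene lists compare with random genes.

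Genes named for late against early are, per direction, the 12 with the most called regions and then up to 4 members of each list with a called region, ordered by number of called regions, with ties by smallest adjusted p and then position. Single regions named are the 5 per direction with the smallest adjusted p among those also unanimous at 72 h against 0 h, with ties by rank. Some genes and regions that these rules pick are left out of the text. The groups, tests, gene lists, motifs, naming rules and alternatives were fixed before the data were examined. The alternatives were full lists, lists of 14631 peaks, an overlap of 1 bp, a summit inside the window, a merged union of peaks, each set alone, other definitions of late, other strata, a distance of 20 kb, the whole window for motifs, no GC strata, and leaving out each library. Chosen after seeing the data were the comparison without the 24 h libraries, the splits that mix the 4 libraries of 2 times of one set, the 100 drawn splits of the 18 libraries, the motif shares per library, the genes named at 72 h and 3 h against 0 h, and the motif and gene list tests on the unanimous regions, which used as background the other regions present in exactly 4 of the 8 libraries. That background was itself put in place after results with another had been seen: the motif tests were first run against regions in 4 to 8 of the 8 libraries, and promoter shares of unanimous regions were first compared with regions in all 8. It was changed because only regions in exactly 4 of the 8 could have met the unanimous criterion.

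The exact test was tested on simulated data for late against early, over 31344 regions. Of 200 planted regions present in 95% of the libraries on one side and 5% on the other, 78 (39.0%) were recovered. Of 200 planted regions present in 80% on one side and 20% on the other, 1 (0.5%) was recovered, and 0 unchanged regions were called. The adjustment depends on how many regions change, so these rates do not give the recovery in the real data. There, called regions had an unadjusted p of at most 0.0022 (exact stratified Fisher test). Of the 1155 gained and 302 lost calls, 133 and 22 separated all late from all early libraries. Counts for this comparison leave out weaker differences. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and samtools 1.23.1. Peaks on chromosome Y, the mitochondrial chromosome and unplaced or alternate contigs were left out of the comparisons.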

Results

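Open chromatin was measured by ATAC-seq in 20 libraries of H1 human embryonic stem cells during the first 72 h of neural induction by dual SMAD inhibition. The set labelled 3TP had 6 libraries, from 0, 3 and 72 h, and the set labelled 7TP had 14, from 0, 3, 6, 12, 24, 48 and 72 h, with 2 replicates at each time. Peak lists held 30968 to 53941 peaks in the 3TP set and 29263 to 57383 in the 7TP set, covering 7.61 to 27.1 Mb per library. Read depth is unknown. With lists of equal length, 34.8% to 41.6% of a library's regions in the 3TP set lay within 1 kb of a TSS, against 40.8% to 49.2% in the 7TP set. Libraries of one time were more alike than libraries of other times in the same set. The mean Jaccard index was 0.568 over the 10 replicate pairs and 0.488 over the 96 other pairs within a set (permutation p = 1e-05, the smallest that 100000 draws can give). Libraries of one time in different sets had a mean of 0.453 over 12 pairs, below both. The 0 h replicates were the least alike in each set (0.471 in 3TP and 0.522 in 7TP), and in the 3TP set the index between 0 h and 3 h (0.489) was above that of the 0 h pair, as was the index between 0 h and 12 h (0.527) in the 7TP set.

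The first question was which sites differed between stem cells at 0 h and cells after 72 h of induction. Over both sets, 2037 regions were gained at 72 h, present in all 4 libraries of 72 h and in 0 of the 4 of 0 h, and 805 were lost. Both groups lay away from promoters. Within 1 kb of a TSS lay 3.29% of the gained regions (95% exact binomial interval 2.56 to 4.16) and 5.96% of the lost ones (4.43 to 7.83), against 30.2% of the 4759 other regions present in exactly 4 of the 8 libraries (Fisher's exact test, p = 5.3e-168 and p = 1.2e-58). In the motif tests the others are all remaining regions in exactly 4 of the 8 libraries, those called in the opposite direction included. Sequences that homeobox factors of the OTX type bind were found in 21.0% of the gained regions and 3.94% of the others (n = 2037 gained regions, odds ratio 4.53, adjusted p = 6.0e-66), and SOX sequences in 28.4% and 8.03% (odds ratio 3.18, adjusted p = 1.5e-60). The octamer, which POU factors such as POU5F1 bind, was found in 11.9% of the lost regions and 2.44% of the others (n = 805 lost regions, odds ratio 3.6, adjusted p = 1.8e-21). In gained regions its odds ratio over GC strata was 0.466 (n = 2037, adjusted p = 1.3e-06), with unstratified shares of 3.04% in gained regions and 3.59% in the others, and 2.61% in the others of the background used first, regions in 4 to 8 of the 8 libraries. The others here include the 805 lost regions with their 11.9%, so the low odds ratio may rest in part on them. CTCF sequences, which mark insulator sites, occurred in 0.196% of gained regions and 5.30% of the others (n = 2037, odds ratio 0.040, adjusted p = 1.4e-23). The others, also in the promoter comparison, include 1686 regions present in all libraries of one set and none of the other set. Over 1 kb from a TSS, the CTCF share at 0 h was 7.27% in the 3TP set and 3.68% in the 7TP set. The background thus partly reflects the difference between sets. In gained regions the motif of TCF/LEF factors, which act in WNT signalling, had an odds ratio of 2.08 (n = 2037, adjusted p = 1.0e-05), the LHX type homeobox motif 3.50 (adjusted p = 8.8e-11), the RFX motif 2.24 (adjusted p = 0.00053) and the proneural E-box 1.36 (adjusted p = 1.1e-05). In lost regions, RBPJ motifs had an odds ratio of 1.81 (n = 805, adjusted p = 0.00041), and 1.36 with the deposited lists in full (adjusted p = 0.13). These motif tests were chosen after the main comparison had been seen.

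Genes with the most gained regions at 72 h against 0 h were JAG1, a NOTCH ligand, with 5 regions, followed by NNMT, NHS, DMRTA1 and MSI2, with 4 each. VEGFA and CNTN2, a neuronal adhesion molecule, were among those with 3. Among lost regions no gene had more than 2, and CD47, TRIB1 and GALNT7 were among those with 2. These genes were named after their values were seen. Of the fixed lists, the neural ectoderm regulators had 12 gained regions near 10 of 20 genes with a region in exactly 4 of the 8 libraries, 42.9% of such regions against a median of 25.0% in random lists (random-list permutation p = 0.088, adjusted p = 0.82). The WNT pathway list had 9 gained regions, 47.4% against 26.3% (random-list permutation p = 0.084, adjusted p = 0.82). Gained shares were 53.8% of 13 regions for the NOTCH list (30.8% in random lists, random-list permutation p = 0.23), 46.2% of 13 for SMAD pathway targets (30.8%, random-list permutation p = 0.30) and 42.9% of 14 for mesendoderm (28.6%, random-list permutation p = 0.54), with an adjusted p of 1.0 for each. Near pluripotency genes 5 of 18 regions were lost, 27.8% against 5.56% (random-list permutation p = 0.015, adjusted p = 0.42), and 4 were gained. No list passed adjustment with lists of equal length, and with the deposited lists in full mesendoderm passed for gained regions (random-list permutation, adjusted p = 0.036). Within the 3TP set alone 5805 regions were gained and 3836 lost, and within the 7TP set alone 4595 and 3816; with the deposited lists in full these were 10828 and 3032 (3TP) and 4198 and 6271 (7TP), so that in the 7TP set the balance turned from more gained to more lost. Leaving out 1 library raised the lost count to 1271 (3TP 0 h replicate 1), 1217 (3TP 0 h replicate 2) and 1244 (7TP 0 h replicate 2). Such a count can only stay or rise when a library is left out, since fewer libraries have to be unanimous.

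The next comparison asked what changed within the first 3 h. Over both sets 220 regions were gained at 3 h against 0 h and 120 were lost. These were 6.13% of the 5544 regions present in exactly 4 of the 8 libraries, against 2.86% if presence fell at random over the libraries. A part of them may thus have arisen by chance. A difference in promoter share was not detectable for gained regions, with 27.7% (95% exact interval 21.9 to 34.1) within 1 kb of a TSS against 26.6% of the 5204 others present in 4 of the 8 libraries (Fisher's exact test, odds ratio 1.06, p = 0.70), a background put in place after a first comparison, with the regions in all 8 libraries, of which 71.6% were at promoters. Lost regions were at promoters less often, at 8.33% (4.07 to 14.8, p = 9.1e-07 by Fisher's exact test). The POU octamer was found in 14.5% of the gained regions and 3.51% of the 5324 others, here with the lost regions included (n = 220, odds ratio 5.55, adjusted p = 3.5e-16). The motifs of RFX (n = 220, odds ratio 4.45, adjusted p = 0.00033), NFY (2.57, adjusted p = 0.0029) and SP/KLF (2.18, adjusted p = 0.015) were also more frequent in gained regions, and with the deposited lists in full the adjusted p of these was 0.21, 0.097 and 0.059. Against the background of the first run, regions in 4 to 8 of the 8 libraries, the odds ratio was 4.24 for the octamer (n = 220, adjusted p = 4.4e-12), 3.52 for RFX (adjusted p = 0.0027), 1.11 for NFY (adjusted p = 1.0) and 1.42 for SP/KLF (adjusted p = 0.69). The octamer was the only one of the 4 that passed in each of these settings. Gained regions lay near 172 genes, of which 1, IGBP1, had 2. Of the list members, POU3F3, SMAD7, PAX7 and TWIST1 each had 1 gained region and 0 had a lost one. SMAD7 is an inhibitor induced by TGF-beta signalling and POU3F3 a neural POU factor.

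The 340 regions gained or lost at 3 h compare with 1642 for the split of the 3TP against the 7TP libraries and at most 270 for the other 33 splits. Those 1642 regions are among the others used as background for promoters and motifs at 3 h. Within the 3TP set alone 2755 regions were gained and 1674 lost, a total of 4429 against 2588 and 2528 for splits that mixed the 4 libraries, and within the 7TP set alone 2779 and 2062, a total of 4841 against 2097 and 2013. Leaving out a library can only keep or raise these counts, since fewer libraries have to be unanimous. Without any 1 of the 8 libraries the gained count rose to between 350 and 513. The lost count rose to between 166 and 317, and by over 1.5 times without the 3TP 0 h replicates (310 and 317), the 7TP 0 h replicates (217 and 254) or 3TP 3 h replicate 2 (188). With the deposited lists in full 479 were gained.

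Followed in the 7TP libraries that took no part in their definition, the 220 regions gained at 3 h were called in 62.5% ± 4.18 of cases at 6 h (SD, n = 2), 32.5% ± 4.18 at 12 h, 20.7% ± 0.321 at 24 h, 31.1% ± 0.321 at 48 h and 25.9% ± 2.57 at 72 h. In the 72 h libraries of the 3TP set they were called in 21.6% ± 1.61. The 120 lost regions were called in 27.9% ± 2.95 at 6 h and in 55.8% ± 10.6 at 12 h, 67.5% ± 7.07 at 24 h, 50.4% ± 6.48 at 48 h and 31.7% ± 9.43 at 72 h, in the same 7TP libraries. The plot of regions gained at 3 h divides them by presence of the octamer.

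**Figure D1:**
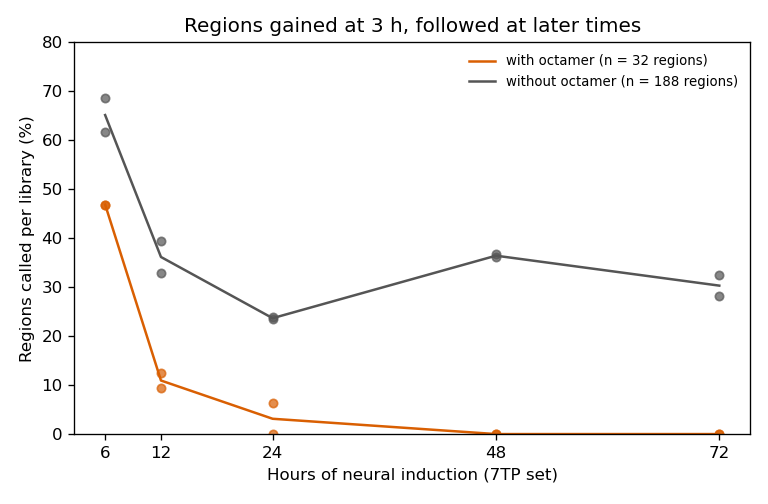
Percent of the regions gained at 3 h that were called in each later 7TP library (points) and the mean of both replicates (lines), for the 32 with and the 188 without an octamer. With an octamer the mean goes from 46.9% at 6 h to 0% at 48 h, and without one from 65.2% to 36.4%. The groups differ in their share of regions within 1 kb of a TSS, which the plot does not adjust for.

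Against 3 h in place of 0 h, 2320 regions were gained at 72 h and 1192 lost, of which 2.63% and 12% lay within 1 kb of a TSS, against 30.0% of the 4157 others. In the 3TP set alone these counts were 5889 and 5231, and in the 7TP set alone 4438 and 4476. With the deposited lists in full 1964 were lost.

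The time course of the 7TP set shows when the 72 h state appeared. Regions gained at 72 h in the 3TP set (5805) were called in 14.8% ± 1.10 of cases at 0 h (SD, n = 2), 14.7% ± 0.268 at 3 h, 15.7% ± 0.146 at 6 h, 17.3% ± 0.171 at 12 h and 22.8% ± 0.548 at 24 h. At 48 h they were called in 48.6% ± 0.439 and at 72 h in 61.1% ± 5.07. Regions lost at 72 h in the 3TP set (3836) were called in 51.6% at 0 h, 51.0% at 3 h, 49.9% at 6 h, 50.7% at 12 h, 46.5% at 24 h, 32.1% at 48 h and 21.2% at 72 h. Over the 14 libraries the share of gained regions rose with time (Pearson r = 0.98, Spearman rho = 0.97, permutation p = 1e-05 for each, the smallest that the draws can give; adjusted over both directions 1e-05 and 2e-05), and without the 72 h libraries r was 0.96. The share of lost regions fell with time (r = -0.98, permutation p = 1e-05; rho = -0.82, permutation p = 0.00062), and r was -0.94 without the 72 h libraries. Over the 7 libraries numbered 2 alone, rho for lost regions was -0.68 (exact permutation p = 0.11), and over those numbered 1 it was -0.96 (exact permutation p = 0.0028).

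**Figure D2:**
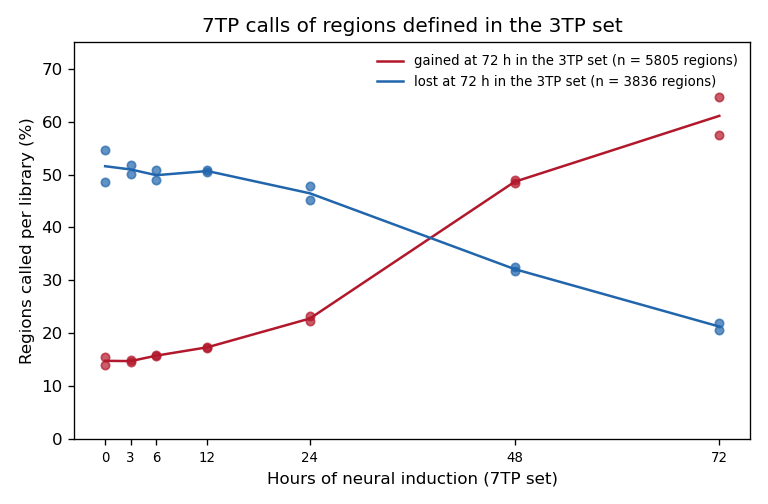
Percent of regions called in each 7TP library (points) and the mean of both replicates (lines) against hours of induction, for regions gained or lost at 72 h in the 3TP set. The gained regions go from 22.8% at 24 h to 48.6% at 48 h while the lost ones go from 46.5% to 32.1%.

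Between neighbouring times of the 7TP set, 48 h against 24 h had the most regions that differed in both replicates, with 3712 gained and 2914 lost. Splits that mixed these 4 libraries gave totals of 1899 and 1754, below the total of 6626. From 3 h against 0 h the total was 4841, the second highest, from 6 h against 3 h 3145, from 12 h against 6 h 4174, from 24 h against 12 h 4344 and from 72 h against 48 h 4111, where mixed splits gave between 2013 and 2453. With 2 against 2 libraries no share of splits can fall under 0.05. In similarity, 24 h libraries had a mean Jaccard index of 0.514 with 12 h, 0.491 with 0 h and 0.484 with 48 h, and 48 h libraries had 0.558 with 72 h. The libraries of 3, 6 and 12 h were nearer to 48 h (0.514, 0.504 and 0.508) than those of 24 h, and only 0 h was further (0.480). With 72 h the index was 0.427 for 24 h and 0.431 for 0 h. The 24 h libraries also had the lowest promoter shares of the 7TP set (40.8% and 41.1%). What part of the 6626 regions comes from this was not tested.

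Late libraries (24, 48 and 72 h) were then compared with early ones (0, 3 and 6 h). Of 31344 regions tested, 1155 were gained and 302 lost, with a median of 6 of 8 late and 0 of 10 early libraries for gained regions and 1 of 8 and 10 of 10 for lost ones. Of these, 951 gained and 193 lost regions were also unanimous at 72 h against 0 h. Gained regions were distal, with 54.2% intergenic, 42.3% in introns and 2.16% within 1 kb of a TSS, against 22.7% within 1 kb for the regions not called (Fisher's exact test, odds ratio 0.075, p = 2.8e-89). For lost regions that share was 8.28% (Fisher's exact test, odds ratio 0.307, p = 6.4e-11). The median distance to a TSS was 68.0 kb for gained, 30.4 kb for lost and 25.4 kb for other tested regions. The 5 gained regions chosen by rank were present in 8 of 8 late and 0 of 10 early libraries (exact stratified Fisher test, p = 7.2e-05, adjusted p = 0.015 for each). They were an intron of PLCH1, a phospholipase C (hg19 chromosome 3, 155432061 to 155432561), an intron of GLRA1, a glycine receptor subunit (chromosome 5, 151297367 to 151297867), an intergenic site 23 kb upstream of TSKU (chromosome 11, 76470118 to 76470618), an intron of TNS1 (chromosome 2, 218700899 to 218701399) and an intron of CADPS2 (chromosome 7, 122407322 to 122407822). Lost ones chosen in the same way, in 0 of 8 and 10 of 10, included intergenic sites near OR2V2 (chromosome 5, 180600844 to 180601344) and PSMG3 (chromosome 7, 1616374 to 1616874), an intergenic site 1461 kb from PCDH9 (chromosome 13, 66342615 to 66343115) and an intron of TLE2 (chromosome 19, 3006099 to 3006599), a corepressor.

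NAV1, MEIS1 and MSI2 had the most gained late regions, with 3 each of 13, 9 and 11 tested. MEIS1 is a homeobox factor of the neural ectoderm list and MSI2 an RNA-binding protein of neural progenitors. GLI3, the transcription factor of hedgehog signalling, had 2 of 9, as had AFF3 (of 5), RBMS1 (of 5), KCNN2 (of 6), PLEKHA7 (of 8), TSKU (of 6), RTL1 (of 4), HERC1 (of 5) and LDLRAD4 (of 8). Among lost regions KRBA1, ARHGAP42 and HAPLN3 had 2 each, and SEMA4A, MRPS22, OR2V2, PSMG3, PIWIL4, AMHR2, FLT1 and ENSG00000259060 were among those with 1.

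The neural ectoderm list had 6 gained regions among 120 tested, 5.0% against a median of 3.36% in random lists. They lay near MEIS1, SOX1, FEZF2 and FEZF1. The region 37 kb downstream of SOX1, an early neural marker, was present in 8 of 8 late and 0 of 10 early libraries (chromosome 13, 112758203 to 112758703; exact test, adjusted p = 0.015), and those of FEZF2 and FEZF1, forebrain regulators, in 6 of 8 and 0 of 10. In the same list, 1 region each near OTX2 (0 of 8 late, 8 of 10 early) and PAX6 (0 of 8, 6 of 10) was lost, while at 72 h against 0 h OTX2 had 1 region gained and 1 lost and PAX6 had 1 gained and 0 lost. Adjusted over the list alone, 7 regions were gained and 2 lost. The pluripotency list had 3 lost regions, 1 each near VRTN, DPPA4 and NODAL, of 53 tested (5.66% against 0%, random-list permutation p = 0.027, adjusted p = 0.80), and 3 gained ones, near KLF4, MYCN and DNMT3B. Adjusted over the list alone, 3 were gained and 6 lost.

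SMAD pathway targets had 3 gained regions, 2 near TGIF1, a SMAD corepressor, and 1 near MSX1, a homeobox target of BMP signalling, and 1 lost region, near NODAL. Adjusted over the list alone, 3 were gained and 1 lost. The WNT pathway list had 5 of 58 gained (8.62% against 3.45%, random-list permutation p = 0.12), near SFRP1, AXIN2, FZD7 and FZD5, and 0 lost. Adjusted over the list alone, 6 were gained. JAG1 had both gained regions of the NOTCH list, which had 0 lost and 3 gained when adjusted over the list alone. Of the FGF and ERK feedback list, DUSP6, SPRY2 and FGFR1 had a gained region each and FGFR1 and ETV4 a lost one each, and adjusted over the list alone 6 were gained and 4 lost. NEUROG2, a proneural factor of the neuronal list, had 1 gained region.

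Markers of other cell types were tested in the same way. GSC had both gained regions of the mesendoderm list, 5.26% of its 38 tested regions (11 gained and 1 lost when adjusted over the list alone). TP63 and CDX2 had 1 each in the trophoblast and surface ectoderm list, 7.14% of 28 (3 gained adjusted over the list alone), PAX3 had 1 and SOX9 lost 1 in the neural crest and placode list (1 of each adjusted over the list alone), and POSTN had 1 in the fibroblast list (1 gained adjusted over the list alone). MYC lost 1 region of the immediate early list (0 adjusted over the list alone) and HOXC4 1 of the HOX list (1 adjusted over the list alone). Blood and endothelium and housekeeping lists had 0 called, and 0 when adjusted over the list alone. Of the 30 tests of lists and directions, 0 passed adjustment, and the lowest adjusted p was 0.80.

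Motifs separated the late regions by direction. SOX sequences were found in 29.9% of gained regions and 9.42% of the other tested regions (n = 1155, odds ratio 2.88, adjusted p = 2.0e-58) and OTX type sequences in 19.5% and 5.30% (odds ratio 2.85, adjusted p = 1.5e-41). LHX type (n = 1155, odds ratio 2.19, adjusted p = 4.0e-06), TCF/LEF (1.68, adjusted p = 0.0038) and proneural E-box sequences (1.27, adjusted p = 0.0038) were also more frequent in gained regions. With the deposited lists in full, LHX type and TCF/LEF did not pass (n = 552, odds ratios 1.26 and 1.54, adjusted p = 0.72 and 0.25). The POU octamer was found in 18.9% of lost regions against 3.80% (n = 302, odds ratio 4.57, adjusted p = 6.3e-26), and its odds ratio in gained regions was 0.476 (adjusted p = 6.8e-05), which did not pass without GC strata (0.799, adjusted p = 0.38) or with the deposited lists in full (0.530, adjusted p = 0.063). AP-1 sequences, bound by FOS and JUN factors, had an odds ratio of 2.40 in lost regions (n = 302, adjusted p = 4.3e-05) and 0.513 in gained ones (adjusted p = 0.0026; 0.654 without GC strata, adjusted p = 0.063). CTCF sequences were found in 0.087% of gained regions against 4.37% (n = 1155, odds ratio 0.020, adjusted p = 2.7e-11). GC content averaged 48.7% ± 6.44 (SD over 1155 regions) in gained, 51.9% ± 8.71 (302) in lost and 56.8% ± 11.5 (29887) in other regions, and GC was a stratum in each of these tests. TFAP2 and TEAD sequences in gained regions turned direction when GC was left out.

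**Figure D3:**
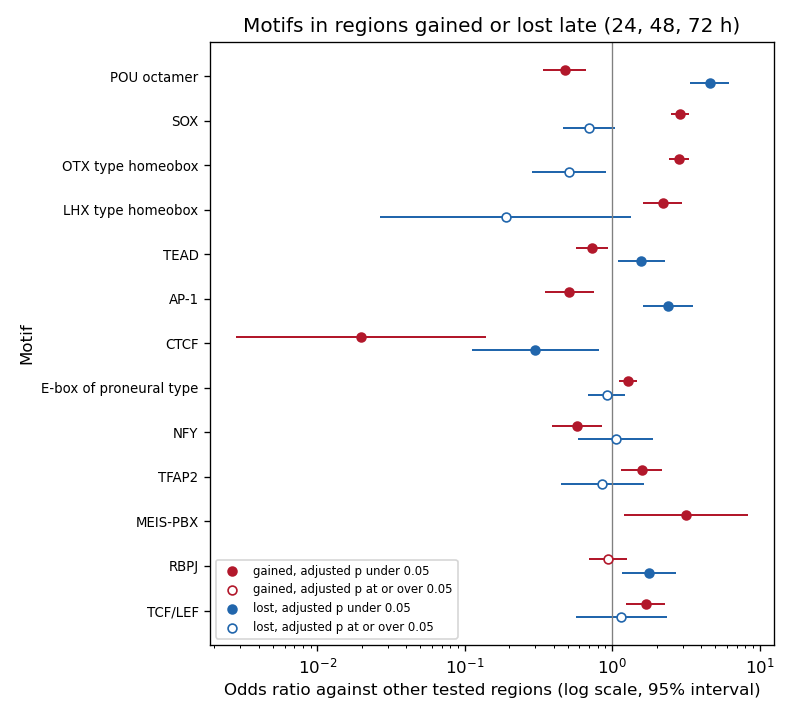
Odds ratio with 95% interval (log axis) of each motif that passed adjustment in at least one direction, for regions gained (red) or lost (blue) in late against early libraries; filled points passed adjustment. SOX and OTX type motifs lie to the right for gained regions (2.88 and 2.85) and the POU octamer for lost ones (4.57); MEIS-PBX had no match in lost regions and has no point there.

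Among regions over 1 kb from a TSS, the share with an octamer was lower at 72 h than at 0 h in each set, at 3.25% ± 0.0127 against 4.77% ± 0.259 in the 7TP set and 3.34% ± 0.0608 against 4.84% ± 0.0212 in the 3TP set (SD, n = 2 each), as the plot of motif shares per library shows. These shares were computed after the calls had been seen.

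**Figure D4:**
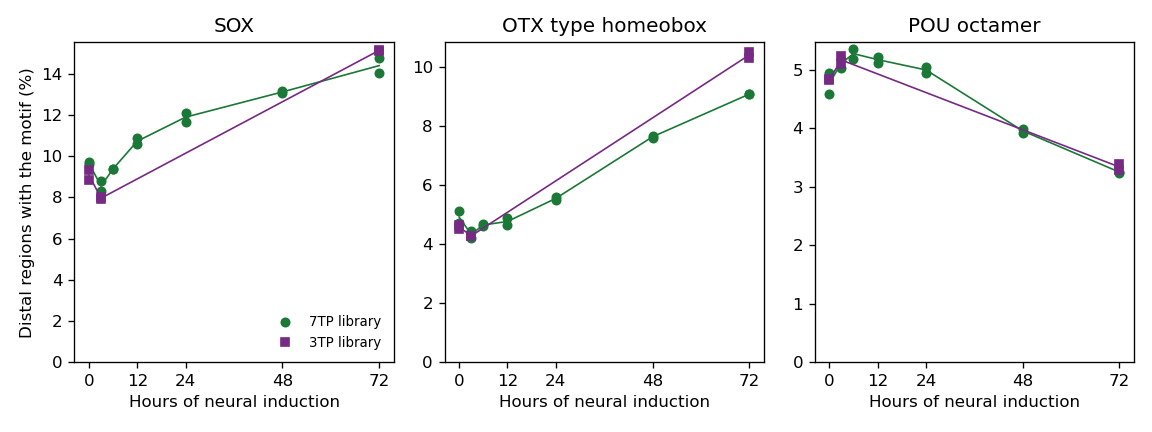
Percent of a library's regions over 1 kb from a TSS that hold a SOX, OTX type or POU octamer motif, against hours of induction, for 7TP (circles) and 3TP (squares) libraries with lines through the means. SOX goes from 9.66% to 14.4% and OTX type from 4.91% to 9.08% between 0 and 72 h of the 7TP set.

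The count of regions called late against early varied with the libraries used. Calls such as that of FEZF2, in 6 of 8 late and 0 of 10 early libraries, had an adjusted p of 0.044 (exact stratified Fisher test). Leaving out a library changes the p-values that the test can give, so calls tied near the threshold pass or fail together. The spread of counts thus does not show that single libraries drive the difference. Leaving out any 1 of the 18 libraries other than 3TP 0 h replicate 1 or either 24 h library lowered the gained count to between 138 and 494, and the lost count to between 22 and 122. Without 3TP 0 h replicate 1 the counts were 1312 and 464. With the deposited lists in full they were 552 and 115, with 12 h counted as late 16 and 6, with no filter on libraries 133 and 22, and without the 24 h libraries, an alternative chosen after seeing the data, 1853 and 499. Within the 7TP set alone the exact stratified test called 0 regions, where 1142 had an unadjusted p under 0.05 and the smallest adjusted p was 0.14. The smallest unadjusted p, 0.0022 in 256 of 16829 regions, is the lowest that these libraries can give in this test. Even regions with full separation therefore did not pass, and the 0 does not show that the sets disagree.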

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

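The tests of groupings below were written out after the results had been seen, though a comparison with the 35 splits of 8 libraries was in the plan fixed beforehand. For 72 h against 0 h, 1 of the 35 splits of the 8 libraries, the real one, gave as many regions (2842). The highest of the others was 1686, the split of the 3TP against the 7TP libraries, and the rest gave at most 217. Most of these splits break up replicate pairs, which may be technical. Those with 2 libraries of each set per side are too few for a share under 0.05. The real split thus gave the highest count, which does not by itself exclude chance between cultures. For 72 h against 3 h, 1 of 35 splits, the real one, gave 3512, and the highest other was again the split by set with 1469. The rest gave at most 252, and the same limit holds. For 3 h against 0 h, 2 of 35 splits gave as many as the real 340, with 1642 for the split by set and at most 270 for the other 33, so this share does not exclude chance for that count. The split by set calls several times the real count at 3 h and follows a structure of the samples. Within each set, 3 h differed from 0 h by 2755 gained and 1674 lost regions (3TP) and by 2779 and 2062 (7TP), and splits that mixed the 4 libraries of a set gave totals of at most 2588 and 2097; 2 against 2 libraries cannot give a share of splits under 0.05. For late against early, 1 of 100 drawn splits, the real one, gave 1457 calls, and the highest other gave 0. These splits also move single libraries and break up replicate pairs, so this share does not exclude chance between cultures.

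The number of deposited peaks changed in opposite ways in the sets. From 0 h to 72 h it rose by a mean of 12986 in the 3TP set (11913 and 14059 for the replicate numbers) and fell by 9738.5 in the 7TP set (it fell by 14027 and fell by 5450). A test of this difference by leaving out libraries was run, gave no decision, and was dropped after its result was seen, because leaving out a library loosens the criterion of one side; no other test was made. With the deposited lists in full, the 3TP set gained 10828 and lost 3032 regions at 72 h and the 7TP set gained 4198 and lost 6271; with lists of equal length the 7TP set gained 4595 and lost 3816.

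Peaks on unplaced or alternate contigs, which no comparison used, numbered 91.3 on average in a 3TP library and 23.9 in a 7TP library.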

How the results depend on the processing

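The share of regions over time and the similarity of replicates kept their direction and their side of the threshold under each alternative run, apart from the lost regions over the 7 libraries numbered 2 alone (rho = -0.68, exact permutation p = 0.11). An overlap of 1 bp, a summit inside the window, a merged union of peaks and, for late against early, no set strata moved each region count by at most 1.5 times. With the deposited lists in full, 479 regions were gained at 3 h against 0 h, 1964 were lost at 72 h against 3 h, and 552 and 115 were gained and lost late. With lists of 14631 peaks, gained and lost counts were 982 and 314 at 72 h against 0 h, 105 and 55 at 3 h against 0 h, 1117 and 425 at 72 h against 3 h, and 218 and 39 late, which follows from fewer peaks. Within the 3TP set alone, where 2 libraries of each time need to be unanimous in place of 4, they were 5805 and 3836, 2755 and 1674, and 5889 and 5231. Within the 7TP set alone they were 4595 and 3816, 2779 and 2062, and 4438 and 4476. Late against early they were 0 and 0 in that set, where even full separation did not pass adjustment. Late against early gave 16 and 6 with 12 h counted as late, 133 and 22 with no filter on libraries, and, chosen after seeing the data, 1853 and 499 without the 24 h libraries, of which 1066 gained and 236 lost regions were among the main calls. With lists in full, the 7TP set alone turned to 4198 gained and 6271 lost at 72 h against 0 h. The late counts with no filter, 133 and 22, equal the numbers of main calls that separated all late from all early libraries. For late against early, calls with tied p-values close to the threshold pass or fail together when the libraries or the filter change. Other causes of these shifts were not tested. The replicate numbers do not pair the samples: the correlation of deviations between same-numbered libraries lay between -0.0080 and 0.014 over 24 pairs of times and 0 were over 0.1. With set and replicate number as a block, late against early gave 0 gained and 0 lost, by an exact stratified test whose smallest p was 0.00028 and smallest adjusted p 0.056, while 5747 regions had an unadjusted p under 0.05. That smallest p is the lowest that the blocked test can give, and 155 regions had it. Even regions with full separation therefore did not pass, so the 0 and 0 do not show that blocking removes the difference. Leaving out each library in turn gave 2165 to 2776 gained and 874 to 1271 lost regions at 72 h against 0 h, 350 to 513 and 166 to 317 at 3 h against 0 h, and 138 to 1312 and 22 to 464 late. The unanimous counts can only stay or rise in this way, since fewer libraries have to be unanimous. Without GC strata, the odds ratio in regions gained late was 1.04 for TEAD (n = 1155, adjusted p = 0.94) and 0.605 for TFAP2 (adjusted p = 0.0032), the reverse of the stratified values of 0.730 and 1.59; GC strata are the only difference. At 3 h against 0 h, NFY and SP/KLF in gained regions passed against regions in exactly 4 of the 8 libraries and not against those in 4 to 8, the background used first (odds ratios 1.11 and 1.42, n = 220, adjusted p = 1.0 and 0.69); both backgrounds were chosen after seeing the data. SOX and OTX type motifs in gained regions and the POU octamer in lost ones passed under each of the 3 motif alternatives; LHX type and TCF/LEF motifs and the low octamer odds ratio in regions gained late did not pass with lists in full. Gene lists passed adjustment in no alternative, except mesendoderm at 72 h against 0 h with lists in full, chosen after seeing the data (random-list permutation, adjusted p = 0.036).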

Other observations

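Motif shares could also be read in each library, without any call of gained or lost regions. This was chosen after seeing the data, as were all tests of this part except those named as set beforehand. Among regions over 1 kb from a TSS, SOX sequences were found in 9.66% at 0 h of the 7TP set, 8.55% at 3 h, 11.9% at 24 h and 14.4% at 72 h (r = 0.95, rho = 0.89 over 14 libraries, permutation p adjusted over 26 motifs 8.7e-05 and 0.0010), and in 9.09%, 7.96% and 15.1% at 0, 3 and 72 h of the 3TP set. OTX type sequences went from 4.91% to 9.08% (r = 0.98, rho = 0.80, adjusted permutation p = 8.7e-05 and 0.0064), TCF/LEF sequences from 1.69% to 2.45% (r = 0.95, adjusted permutation p = 8.7e-05) and proneural E-boxes from 18.8% to 21.5% (r = 0.81, rho = 0.95, adjusted permutation p = 0.0023 and 0.00026). Without the 72 h libraries, r was 0.93, 0.95, 0.92 and 0.76 for these motifs. POU octamers were found in 4.77% at 0 h, 5.28% at 6 h, 3.96% at 48 h and 3.25% at 72 h, with r = -0.92 (adjusted permutation p = 0.00048) and rho = -0.55 (adjusted permutation p = 0.10). AP-1 sequences were found in 3.84% at 0 h, 6.27% at 6 h and 3.42% at 72 h, and their odds ratio in regions gained at 3 h was 2.05 with lists of equal length (n = 220, adjusted p = 0.092), which did not pass, and 2.70 with the deposited lists in full (n = 479, adjusted p = 1.7e-07). In regions lost at 3 h it was 2.16 with lists of equal length (n = 120, Cochran-Mantel-Haenszel test, adjusted p = 0.13), so these lists show no direction for AP-1 at 3 h.

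One pattern to follow up is at octamer sites: of the 220 regions gained at 3 h, the 32 with an octamer were called in 46.9% of cases at 6 h, 10.9% ± 2.21 at 12 h (SD, n = 2), 3.12% ± 4.42 at 24 h and 0% in each library of 48 and 72 h of the 7TP set, and in 4.69% at 72 h of the 3TP set. The 188 without one were called in 65.2%, 36.2%, 23.7%, 36.4% and 30.3% at these times. An octamer was found in 18.9% of the 159 gained regions over 1 kb from a TSS and in 3.28% of the 61 within 1 kb. Regions with and without one thus differ in promoter share, and their later calls were not compared at an equal share. A test set beforehand concerned the handling of one set. Taken alone, the octamer's odds ratio over GC strata in regions gained at 3 h was 2.34 in the 3TP set (95% interval from 1.88). In the 7TP set it was 2.69. The unstratified shares were 5.52% against 3.70% (3TP) and 4.75% against 3.73% (7TP). Both lists hold the same 220 regions in which the pattern was found. The test was not run without these regions, so it does not decide the question. Another test set beforehand concerned a larger share of promoters in the 3 h lists. Over 1 kb from a TSS the odds ratio was 6.16 (interval from 3.91), and within 1 kb 1.76 (0.387 to 8.03, n = 61). Among the other regions octamers were rarer within 1 kb (1.22%) than beyond (4.32%). More promoters would thus lower the octamer share, so this test could hardly have come out otherwise. GC content was argued against by the GC-stratified interval, which began at 3.61. These odds ratios concern the enrichment at 3 h and not the later calls. Choosing regions by their presence at 3 h lowers later shares of both kinds, the share of splits did not exclude chance for the number of regions at 3 h, and batch effects common to the 3 h libraries of both sets stay open.

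A second pattern is a step between 24 and 48 h, with the share of 72 h regions going from 22.8% at 24 h to 48.6% at 48 h. Weak enrichment in the 24 h libraries could lower calls of any region, and regions present in all 6 libraries of the 3TP set were called in 82.9% ± 0.725 at 24 h (SD, n = 2), below 89.0% at 12 h and 90.0% at 48 h. A test set before its result was seen, in place of one on lost regions, which were chosen for their fall, argued against it as the whole of the step: in 3873 regions not chosen for a change (in 1 of 2 libraries at 0 h and 1 of 2 at 72 h of the 3TP set), called in 38.7% ± 2.25 at 24 h and 45.7% ± 0.639 at 48 h (SD, n = 2), the lowest ratio of a 24 h to a 48 h library was 0.803, which is 0.324 above the highest ratio in gained regions, 0.479, so a part of the step stays open to it. List length was tested beforehand: in lists of 14631 peaks the rise from 24 to 48 h was 16.5 percentage points above the highest rise between earlier neighbouring times, and in full lists 24.1. The steps before 24 h are shorter, and over the 24 h from 0 h the share went from 14.8% to 22.8%. The 24 h libraries were less like those of 48 h (Jaccard index 0.484) than the libraries of 3, 6 and 12 h were (0.514, 0.504 and 0.508). Whether 24 and 48 h libraries were made in one batch is not given in the sources used here, so a batch stays open.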
